A study of Danio rerio with 6 samples.

How the data were processed

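Whole kidney marrow of 10 adult zebrafish was profiled by inDrops, a droplet method that barcodes the poly(A) RNA of single cells and tags each captured molecule with a unique molecular identifier (UMI). Per the labels, cells were suspended in 15% Optiprep, RNA of a set number of cells per animal was pooled and libraries were sequenced on an Illumina NextSeq instrument. The animals comprised 3 wild type fish of the casper strain, 3 prkdc(D3612fs) homozygotes, 2 il2rga(Y91fs) mutants and 2 fish carrying both mutations, called double mutants here. Wild type 1 and 2 and prkdc mutant 1 and 2 were prepared with version 2 (V2) of the inDrop protocol as single libraries, and the other 6 animals with version 3 (V3) in 1 pool that was run on the sequencer as 2 technical runs. The runs were not separated in the table and were counted once. The animal was the replicate throughout, with animals assigned through the names carried by the cells.

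The deposited values were UMI counts per gene and cell, a table of 22842 genes by 11327 cells, with no normalization found in the values. Per the submitters' processing notes, Bowtie was used and the genome build was GRCz10, and the deposited pipeline sheet names the indrops pipeline with rsem and samtools as dependencies. Counting that splits reads between near-identical copies was not described in the sources used here, so genes with close paralogs, including the 481 symbols ending in "of_many", are uncertain. Summed counts per cell were at most 162 UMIs below the totals deposited beside the table, in 6070 cells. Gene symbols are given as in the table, in which a point stands for a hyphen or colon. Of them, 18615 (81.5%) matched the RefSeq gene table of assembly GRCz12tu, which was used only for names and for the order of neighbouring genes. No coordinates are given because the builds differ. The mapping metrics of the libraries were not used here.

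Cells were clustered because no cell type annotation was used here. Counts per cell were scaled to 10000, log transformed, reduced to 2000 variable genes and 30 principal components, and joined in a graph of 15 neighbours that was partitioned by the Leiden method at resolution 2 with seed 0, which gave 36 clusters. No filter on cells was added, and the shallowest cell held 361 UMIs. A cluster took the name of a fixed marker set when at least 3 of its markers were at least 2-fold above the other cells, with 10 CPM added (CPM, counts scaled by the total of the cells summed) and at least 5% of its cells positive, and when no unrelated set reached 0.75 of its share of markers (the kidney sets, and the T, NK and NK-lysin sets, were not weighed against each other). A B cell-like cluster with rag1 among its 10 leading genes was kept apart as rag1-high, and clusters led by sycp1 and by krt4 were called meiotic and keratin, splits made after the clusters were seen. Such clusters are called "X-like". Of 14 blood classes, 4 (1100 cells) had no such set and are named by their leading gene. These unnamed clusters were counted as blood without a marker set to show it. No cluster took the fixed marker sets for NK cells, mast cells or eosinophils, podocytes, mucin cells or kidney progenitors, and the proliferation markers named no type. No cluster of a named class held more leading markers of another class than of its own. Doublets were not removed. An own doublet-like score was computed, and the 5% of cells with the highest score in each animal (566 cells) were left out in an alternative only.

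Cell numbers per animal and blood class were tested with edgeR's quasi-likelihood test, with the number of blood cells as library size and Benjamini-Hochberg adjustment over the 14 classes. For expression, raw UMI counts were summed per animal over all blood cells, and per animal within each class with at least 20 cells in at least 2 animals of both genotypes. Sums were tested with edgeR's quasi-likelihood test after TMM scaling and the tool's own filter on low counts, with adjustment over all genes of a fit at 0.05. For cell numbers and for all blood cells, all 10 animals shared 1 fit with genotype and protocol version as terms. A fit within a class held only the animals with at least 20 of its cells, from 5 to 10 animals. The 5 animals of the B cell-like fit were wild type and il2rga mutants, so its version term rests on wild type 3 alone. The il2rga and double mutants were all V3, so elsewhere the version term rests on wild type 3 and prkdc mutant 3 against the V2 animals of those genotypes. Where those V3 animals stand apart, a fitted log2 fold change can differ from the ratio of the means. In il2rga mutants cd74a had a fitted value of 0.65, although its mean was 846 CPM there and 2064 CPM in wild type. Median log2 fold changes over all genes were at most 0.0254.

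Genes named in the text followed a rule fixed before the data were examined. It took prkdc, il2rga, rag1 and rag2, then in each comparison the 12 largest rises and 12 largest falls with adjusted p under 0.05 and a mean of at least 20 CPM in 1 of the genotypes, and up to 4 members of each fixed list by smallest p. Within classes the rule took 5 rises and 5 falls. Other named genes were chosen after their values were seen. Some genes that the rule took are not reported here. The 15 fixed gene lists covered V(D)J recombination, non-homologous end joining, common gamma chain signalling, the p53 response, interferon response, MHC class II, MHC class I, inflammation, neutrophil granules, haemoglobin and haem, dissociation and immediate early genes, mitochondrial transcripts, cytotoxic effectors, complement and proliferation. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 on voom values, and again with an estimated correlation and with fry. Camera compares a list with other genes, fry asks whether its members move on balance in 1 direction, and mixed fry whether they change in either direction. None of the 13 listed mitochondrial genes was in the table, and 2 of the 3 V(D)J genes were, so neither list was tested.

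Alternatives planned ahead were another denominator, no version term, TMM over cell types, only cells above the median UMI count, DESeq2, DESeq2 size factors in edgeR, V3 or V2 animals alone, no filter, cells thinned to 1000 UMIs each, at least 10 or 50 cells per class, a block on the animal number, and leaving out each animal. Alternatives chosen after seeing the data were clustering at resolution 1 (26 clusters, with no T cell-like cluster), clustering without 71 lymphoid genes, leaving out doublet-like cells, leaving out the si.dkeyp.75b4.10 and cfd clusters, leaving out each animal for the wild type shares and the interaction, and the alternatives for the targeted genes. Thinning removed the cells with fewer than 1000 UMIs, from 21 in wild type 2 to 131 in wild type 1. Intervals are 95% exact intervals and floors are 3 counts. Both cover counting error only.

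The statistics were tested on simulated data built from the real means and library sizes. Over all blood cells, the comparison of prkdc mutants with wild type (13897 genes) recovered 0%, 42%, 76% and 87.0% of genes changed 2-, 4-, 8- and 16-fold and called 5 unchanged genes. The il2rga comparison (13868 genes) recovered 0%, 12.8%, 70.2% and 74% with 4 false calls, and the double mutant comparison (13838 genes) 0%, 18%, 66.0% and 74.5% with 9. In erythroid-like cells the il2rga comparison (6872 genes) recovered 64.6% of genes changed 16-fold, with 8 false calls. For cell numbers, falls of 4- and 16-fold were recovered in 35 and 97 of 100 cases for prkdc mutants, 18 and 79 for il2rga mutants and 17 and 73 for double mutants, with 4 to 9 false calls among 600 unchanged tests. A list lowered 4-fold in the il2rga comparison (14380 genes) was called in 20 of 20 draws by camera with either correlation and by fry. With no change, camera with the preset correlation made 5 false calls over 20 draws of 13 lists, camera with an estimated correlation 0 and fry 2. Genes were drawn independently, so these lists lacked the correlation between members that real lists can have. The draws therefore do not show how these tests behave on correlated lists.

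Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Depth ranged from 3618054 UMIs in prkdc mutant 1 to 7495398 in double mutant 1.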

Results

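Single-cell transcriptomes were collected from whole kidney marrow, the tissue in which adult zebrafish form blood, to describe its blood and kidney lineages and to compare fish with known immune defects with wild type. prkdc encodes the catalytic subunit of the DNA-dependent protein kinase, which joins DNA breaks including those of V(D)J recombination, and il2rga encodes a common gamma chain of interleukin receptors. The table held 11327 cells: 3782 from 3 wild type animals, 3201 from 3 prkdc mutants, 2068 from 2 il2rga mutants and 2276 from 2 double mutants. Animals gave 955 to 1380 cells and 3618054 to 7495398 UMIs each. The median was 2098 UMIs per cell in wild type 1 and 2902 to 4709 in the other animals. Blood clusters held 9984 cells, of which 3403, 2722, 1809 and 2050 came from the 4 genotypes. The remaining 1343 cells were 775 of kidney tubule, 281 of endothelium, 154 of stroma, 94 of a cluster led by meiotic genes and 39 of a keratin cluster. The study stated 1699 kidney cells. The rebuilt kidney, endothelial and stromal clusters held 1210, a population defined in another way. Animals of 1 genotype differed from each other far beyond the counting error of UMIs, with chi-square per degree of freedom from 18.6 between the double mutants to 105 between wild type 2 and 3. Wild type 2 and 3 also differ in protocol version, and the V2 pair wild type 1 and 2 was at 58.9. UMIs were treated as independent although each cell holds many. The statistic therefore does not part differences between animals from the sampling of cells.

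The targeted genes were examined first. prkdc was counted at 12.5 ± 3.96 CPM in wild type blood cells (SD, n = 3), 6.93 ± 5.76 in prkdc mutants (n = 3), 22.6 ± 5.89 in il2rga mutants (n = 2) and 7.04 ± 4.39 in double mutants (n = 2). The log2 fold change against wild type was −1.01 (SE 0.43, adjusted p = 0.904) in prkdc mutants and −1.44 (SE 0.56, adjusted p = 0.783) in double mutants. By animal, prkdc was at 9.55, 11 and 17.0 CPM in wild type, 4.62, 2.69 and 13.5 in prkdc mutants, 26.8 and 18.4 in il2rga mutants, and 10.1 and 3.93 in double mutants. il2rga was sparse, at 1.70 ± 0.458 CPM in wild type, 2.12 ± 1.72 in prkdc mutants, 0.456 ± 0.645 in il2rga mutants and 0.305 ± 0.0324 in double mutants, from 26, 26, 6 and 4 UMIs. All 6 UMIs of the il2rga mutants came from il2rga mutant 1. A frameshift need not be visible in the end of the transcript that inDrops counts, so these levels do not check the genotype labels.

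**Figure D1:**
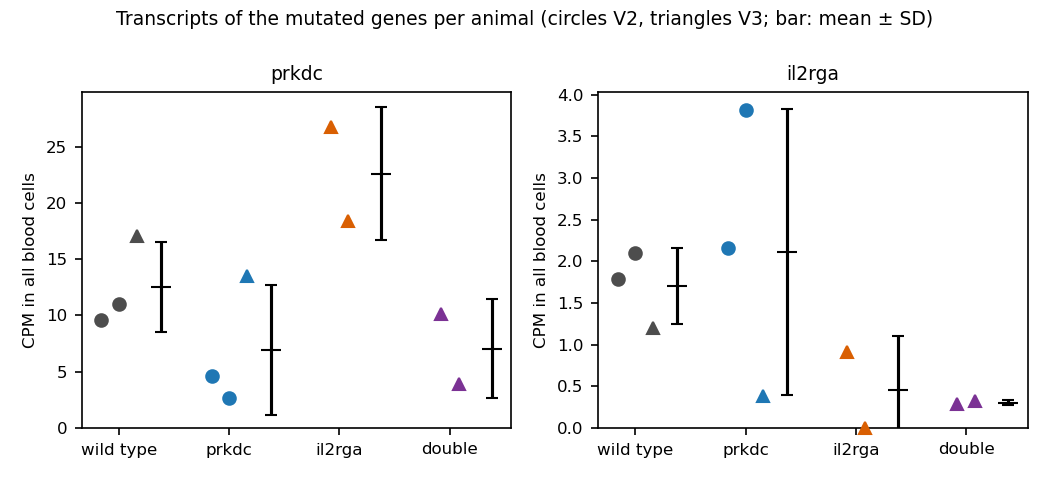
Level of prkdc and il2rga in CPM over all blood cells of each animal, by genotype, with each point 1 animal (circles V2, triangles V3) and bars for the mean ± SD. prkdc averaged 12.5 CPM in wild type and 6.93 CPM in prkdc mutants, with overlapping animals.

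Wild type marrow was dominated by myeloid and erythroid cells. Neutrophil-like cells made up 31.3% ± 13.5 of blood cells (SD, n = 3), macrophage-like cells 21.3% ± 18.7 and erythroid-like cells 16.1% ± 15.3. T cell-like cells made up 5.81% ± 2.45, HSC and progenitor-like cells 5.38% ± 1.34, B cell-like cells 5.05% ± 1.71, NK-lysin cell-like cells 3.47% ± 1.99, thrombocyte-like cells 1.61% ± 0.446, dendritic-like cells 1.36% ± 0.247 and rag1-high B cell-like cells 0.716% ± 0.454. In cells above the median UMI count the T, HSC and progenitor and B cell-like shares were 0.981%, 9.60% and 1.96%. The unnamed clusters led by si.dkeyp.75b4.10, mycb, si.dkey.239h2.3 and cfd held 3.54% ± 2.32, 2.32% ± 0.876, 1.74% ± 1.2 and 0.191% ± 0.166. Myeloid and erythroid shares varied widely: erythroid-like cells ranged from 1.64% in wild type 1 to 32.2% in wild type 3, and macrophage-like cells reached 42.7% in wild type 2.

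Classes were named by marker genes, so their levels describe the classes and do not test the names. Erythroid-like cells held 151260 ± 92130 CPM of the globin ba1 and 3413.6 ± 2365.4 CPM of alas2, the first enzyme of haem synthesis in red cells (n = 3, with 18 such cells in wild type 1). Neutrophil-like cells held 44624 ± 16734 CPM of lyz, lysozyme, and 4945 ± 4012 CPM of mpx, myeloperoxidase (n = 3). Macrophage-like cells held 1096 ± 146 CPM of the scavenger receptor marco, and dendritic-like cells 2470 ± 686 CPM of irf8. T cell-like cells held 788 ± 179 CPM of zap70, a kinase of T cell receptor signalling, against 72.9 in NK-lysin cell-like cells. They held 194 CPM of cd4.1, which was at most 3.12 in any other class. Other T markers parted these 2 classes less. cd8a was at 167 against 57.3 CPM, lck at 121 against 97.4 and itk at 161 against 133. sla2 was higher in NK-lysin cell-like cells (325 against 278 CPM). NK-lysin cell-like cells held 2871 ± 1112 CPM of the chemokine ccl38.6 and 172 ± 62.5 of nkl.2. B cell-like cells held 6072 ± 4636 CPM of the immunoglobulin segment ighv1.4 and 397 ± 98.8 of cd79a. rag1, a recombinase of V(D)J recombination, was at 1665 ± 884 CPM in rag1-high B cell-like cells and 23.4 ± 40.5 in other B cell-like cells. Thrombocyte-like cells held 1190 ± 474.85 CPM of itga2b, an integrin of platelets, against 6.73 in the next class. The HSC and progenitor-like cluster rested on gata2b, meis1b and fli1a and was led by csf1rb and myca. Of its marker list only gfi1aa was highest in this cluster (13.6 ± 14.9 CPM). gata2b was at 67.7 CPM, against 73.1 in the cfd cluster. meis1b and fli1a were at 77.4 and 193 CPM, against 533 and 670 in thrombocyte-like cells. Several myeloid clusters were led by inflammatory genes, including mmp9 in neutrophil-like clusters 3 and 21, il1b in cluster 21, and irg1 and cxcl19 in macrophage-like cluster 14.

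**Figure D2:**
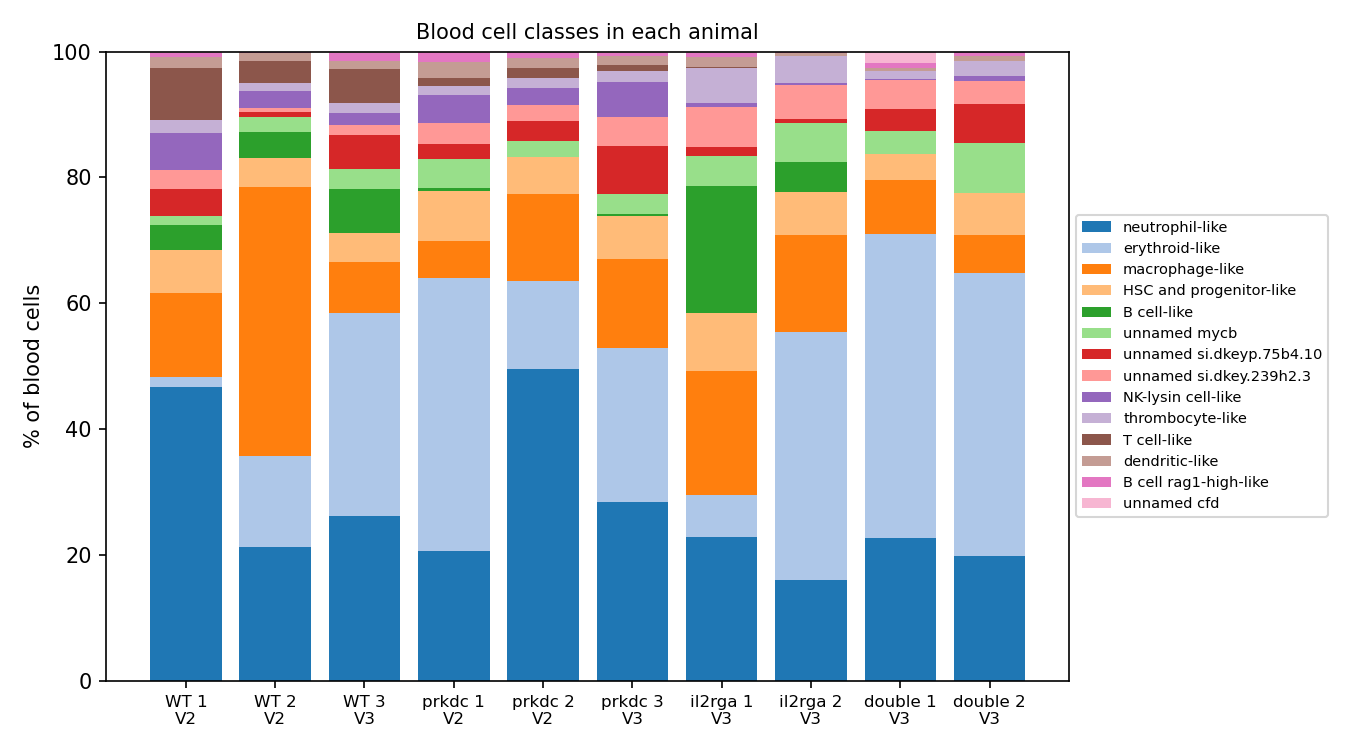
Percent of blood cells (vertical axis) in each of 14 classes for each of 10 animals, as stacked bars ordered by genotype with the protocol version marked. Erythroid-like cells made up 1.64% of wild type 1 and 32.2% of wild type 3, while B cell-like cells were at 0 in both double mutants.

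Loss of prkdc, tested for its effect on lymphoid cells, went with fewer B and T cell-like cells. B cell-like cells fell from 5.05% ± 1.71 of blood cells in wild type to 0.297% ± 0.267 in prkdc mutants (7 of 2722 cells), a fitted 17.4-fold fall (log2 −4.13, SE 0.91, adjusted p = 0.00478, lower in 3 of 3 animals). T cell-like cells fell from 5.81% ± 2.45 to 1.29% ± 0.288 (log2 −2.17, SE 0.67, adjusted p = 0.0336, lower in 3 of 3). NK-lysin cell-like cells were at 4.26% ± 1.41 against 3.47% ± 1.99 (log2 0.32, adjusted p = 0.817), and rag1-high B cell-like cells at 1.03% ± 0.526 against 0.716% ± 0.454 (log2 0.59, adjusted p = 0.817). Erythroid-like cells were at 27.3% ± 14.9 and macrophage-like cells at 11.3% ± 4.63, with adjusted p of 0.769 and 0.782. Within V2 animals the log2 fold changes were −4.08 for B cell-like and −2.04 for T cell-like cells, and within V3 animals −4.18 and −2.45. Both calls were lost in V3 animals alone, which hold 1 animal of each of these genotypes, and with a block on the animal number. The T call was also lost in V2 animals alone (adjusted p = 0.230) and after clustering without lymphoid genes (0.0695). It was lost as well without wild type 1 (0.106), wild type 3 (0.204) or prkdc mutant 1 (0.109), 2 (0.0941) or 3 (0.204).

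Loss of il2rga, likewise tested for its effect on lymphoid cells, went with a near absence of T cell-like cells. They made up 0.0995% ± 0.141 of blood cells (2 of 1809 cells, both in il2rga mutant 1; n = 2), against 5.81% ± 2.45 in wild type. The ratio of the pooled shares was 0.0195 (counting interval 0.00234 to 0.0714; log2 −5.40, SE 1.11, adjusted p = 0.00200), and the log2 value was −5.51 within V3 animals. NK-lysin cell-like cells were at 0.485% ± 0.158 against 3.47% ± 1.99 (log2 −2.70, SE 1.01, adjusted p = 0.0774), lower in both animals than in any wild type but short of the threshold, which it passed without the version term (0.0301). B cell-like cells were at 20.2% in il2rga mutant 1 and 4.85% in il2rga mutant 2 (mean 12.5% ± 10.9; log2 0.86, adjusted p = 0.636). Thrombocyte-like cells were at 4.90% ± 0.950 against 1.61% ± 0.446 (log2 1.60, adjusted p = 0.208). Without wild type 3 the T call was lost (log2 −5.10, adjusted p = 0.0630).

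Double mutants had almost no T cell-like cells and no B cell-like cells outside the rag1-high class. That class stood at 0.725% ± 0.0638 (15 of 2050 cells) against 0.716% ± 0.454 in wild type (adjusted p = 0.958). B cell-like cells numbered 0 of 2050 blood cells, which allows a share of up to 0.146% and is at least 33.7-fold lower than in wild type with a floor over the group (adjusted p = 0.000467). T cell-like cells numbered 1 of 2050, a ratio of 0.00860 (counting interval 0.000217 to 0.0485; log2 −6.40, SE 1.2, adjusted p = 0.000467). Both calls held without each animal in turn. The log2 value of T cell-like cells within V3 animals was −6.50; a fitted log2 value for B cell-like cells is set by the model for a count of 0 and is not given. NK-lysin cell-like cells were at 0.539% ± 0.520 (log2 −2.62, SE 1.00, adjusted p = 0.0820). This difference passed without the version term (0.0222), without double mutant 2 (0.0372) and without the si.dkeyp.75b4.10 and cfd clusters (0.0498). Erythroid-like cells were at 46.7% ± 2.3 (log2 1.1, SE 1.02, adjusted p = 0.460; n = 2).

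The single mutants were set against the double mutants to separate the effects of the mutations. Against prkdc mutants, double mutants had fewer NK-lysin cell-like cells, 0.539% ± 0.520 against 4.26% ± 1.41 (7.66-fold, log2 −2.94, SE 0.94, adjusted p = 0.0417), and fewer T cell-like cells, with a ratio of 0.0369 (counting interval 0.000909 to 0.219, adjusted p = 0.0417). B cell-like cells were at least 1.76-fold lower (adjusted p = 0.131, and 0.0334 without prkdc mutant 2). Against il2rga mutants, B cell-like cells were at least 91.4-fold lower (242 of 1809 cells against 0 of 2050, adjusted p = 0.000226). T cell-like cells did not pass the test (log2 −1.0, adjusted p = 0.680). They numbered 1 of 2050 cells against 2 of 1809, too few for a further fall to be detected. No interaction of the mutations passed edgeR's quasi-likelihood test: 0 of 14 classes, with 1 at an unadjusted p under 0.05, B cell-like cells (adjusted p = 0.203). Their fitted value rests on the count of 0 in double mutants and is not given. For T cell-like cells the interaction rests on the few cells of il2rga and double mutants, too few to decide. DESeq2 was not run for the interaction, and its recovery was not simulated. The calls against prkdc mutants were lost in V3 animals alone (NK-lysin −3.41, adjusted p = 0.0542; T −4.04, 0.106), with DESeq2 (0.0562 for both) and without lymphoid genes in the clustering (0.0631 for both). They were also lost without prkdc mutant 3 (NK-lysin −1.70, 0.619; T −4.48, 0.162), double mutant 1 (−2.14, 0.410; −6.47, 0.122) or double mutant 2 (−4.47, 0.0608; −3.53, 0.217).

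**Figure D3:**
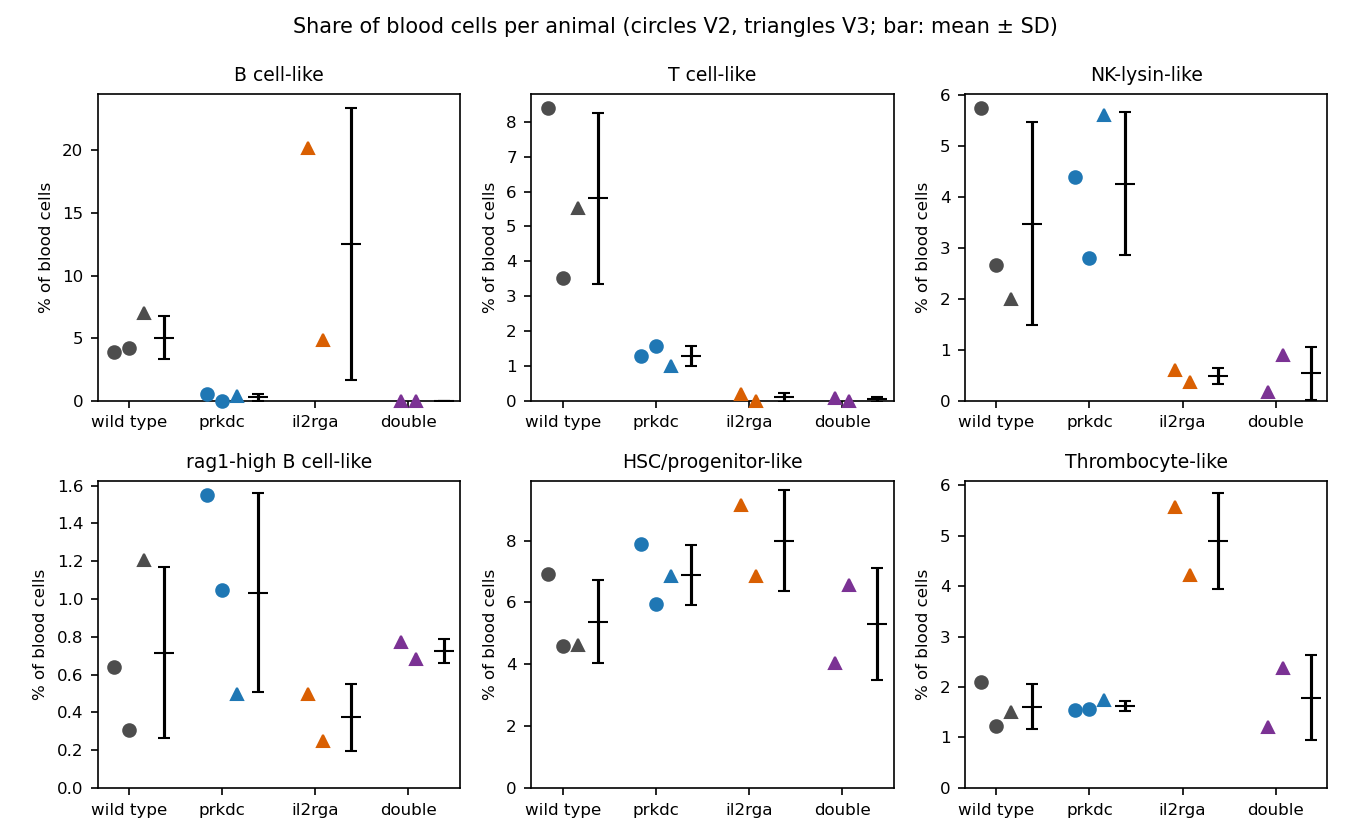
Percent of blood cells per animal (vertical axes, scaled separately) in 6 classes by genotype, with each point 1 animal (circles V2, triangles V3) and bars for the mean ± SD. B cell-like cells fell from 5.05% in wild type to 0.297% in prkdc mutants and 0 of 2050 cells in double mutants, and T cell-like cells from 5.81% to 1.29% in prkdc mutants and 0.0995% in il2rga mutants.

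Over all blood cells of prkdc mutants, no single gene passed the test. edgeR's quasi-likelihood test called 0 of 14380 genes, with 777 at an unadjusted p under 0.05, and DESeq2 called 32. Leaving out wild type 3, prkdc mutant 2 or prkdc mutant 3 gave 1 call each. The recombinase genes were at 8.98 ± 10.3 CPM in wild type and 13.4 ± 12.6 in prkdc mutants for rag1, and at 15.9 ± 9.36 and 15.2 ± 13.7 for rag2 (log2 1.07 and −0.21, adjusted p = 0.942 and 0.979). All 12 tested genes of the inflammatory list had negative log2 fold changes, including il1b, an inflammatory cytokine (−3.38, SE 1.1; 72.3 ± 98.5 CPM in wild type, 3.66 ± 2.14 in prkdc mutants), tnfa (−3.62, SE 1.26) and nfkbiaa, an inhibitor of NF-kappaB (−1.45, SE 0.53). The list was called by camera (adjusted p = 1.1e-05) but not with an estimated correlation (adjusted p = 0.283 with an estimated correlation). The wild type SD of il1b exceeded its mean, and in V3 animals alone il1b and nfkbiaa were at log2 0.04 and 0.26. Likewise 21 of 22 dissociation and immediate early genes were negative, among them dusp1 (301 ± 198 to 152 ± 142 CPM) and atf3 (103 ± 71.7 to 51.4 ± 36.8), as were 7 of 8 MHC class II genes, among them ciita, the class II transactivator (−1.26). Camera called both (adjusted p = 0.000762 for both), with adjusted p = 0.283 with an estimated correlation. The class II gene mhc2dab was at 9.54 and 3.59 CPM in prkdc mutants 1 and 2 and 515 in prkdc mutant 3. In V3 animals alone it was at log2 0.99. Mean B cell-like and macrophage-like shares, given above, were lower in prkdc mutants too.

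In prkdc mutants camera also called the common gamma chain list (12 of 15 negative, with il4r.1 at −1.43; adjusted p = 0.0178, and 0.283 with an estimated correlation) and the neutrophil granule list (11 of 14 negative; 0.0130, and 0.532 with an estimated correlation). It called the interferon list upward (12 of 19 positive; 0.0144, and 0.666 with an estimated correlation), with rsad2, an antiviral enzyme, at 9.47 ± 9.60 CPM against 1.04 ± 0.793 (log2 3.18, SE 0.65, adjusted p = 0.511). All 13 haemoglobin and haem genes were positive (0.0284, and 0.759 with an estimated correlation), hbaa1 at 24644 ± 14484 CPM against 10057 ± 7134.7, beside the wide range of erythroid-like shares. Camera did not call end joining, p53, MHC class I, cytotoxic, complement or proliferation genes (adjusted p = 0.699, 0.0535, 0.426, 0.310, 0.699 and 0.989). Adjusted over the list alone, 1 interferon gene, rsad2, and 1 cytotoxic gene, prf1.2, rose, and the granzyme gene gzma fell, while 0 of them passed over all genes. gzma was at 7.81 ± 3.85 CPM in wild type and 1.3 ± 0.595 in prkdc mutants (log2 −2.44, SE 0.55), and prf1.2, a perforin gene, was at least 16.2-fold higher with a floor over the group (41 against 0 UMIs), with prkdc mutant 3 at 6.46 CPM and prkdc mutants 1 and 2 at 1.85 and 0.224. Fry called 0 lists and mixed fry 1, the cytotoxic genes (4 positive and 3 negative, adjusted p = 0.00460).

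Over all blood cells of il2rga mutants, 2 of 14380 genes were called (718 at an unadjusted p under 0.05). In both, wild type 3 and prkdc mutant 3 differed from the V2 animals of their genotypes. si.dkey.102m7.3, a long non-coding RNA gene, was fitted as a rise (log2 5.99, SE 0.49, adjusted p = 0.00346) from 16.8 ± 14.5 CPM in wild type to 33 ± 3.95, but wild type 3 and prkdc mutant 3 were at 0.687 and 0.38 CPM and the other animals at 15.2 to 36.0. csad, cysteine sulfinic acid decarboxylase of taurine synthesis, was fitted as a fall (log2 −4.37, SE 0.48, adjusted p = 0.0228) from 7.11 ± 11.3 to 0.804 ± 0.153 CPM, with wild type 1 and 2 at 0.895 and 0.324 CPM, wild type 3 at 20.1 and prkdc mutant 3 at 26.6. Double mutants were at 66.3 and 58.3 CPM, so among V3 animals only the il2rga mutants were low. Without wild type 3 no gene was called, and without il2rga mutant 1 or il2rga mutant 2, 1 gene was. Both calls were lost without the version term (log2 1.1 and −3.05) and in cells thinned to 1000 UMIs each (3.61 and −3.64).

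In il2rga mutants 6 of the 7 tested cytotoxic genes had negative log2 fold changes. Camera called the list at the preset correlation (adjusted p = 0.000971) but not with an estimated correlation (adjusted p = 0.759), and fry called 0 lists. Adjusted over the list alone 3 fell and over all genes 0: ccl38.6 (log2 −2.68, SE 0.59; 50.2 ± 24.8 to 5.31 ± 0.847 CPM), gzma, with a ratio of 0.0346 (counting interval 0.00702 to 0.104), and nkl.4, an NK-lysin gene, with a ratio of 0.0233 (0.00476 to 0.0695; wild type 1 at 36 CPM, wild type 2 and 3 at 3.89 and 2.58; log2 −5.44, and −3.91 without wild type 1). These move with the T and NK-lysin cell-like shares given above. In the neutrophil granule list 1 gene, lect2l, fell adjusted over the list alone, from 5989 ± 3038 to 153 ± 77.5 CPM (log2 −4.73, SE 0.66, adjusted p = 0.144 over all genes). The other lists were not called by camera: adjusted p was 0.485 for end joining, 0.532 for common gamma chain, 0.146 for p53 and for MHC class I, 0.649 for interferon, 0.0658 for MHC class II, 0.822 for inflammation, 0.485 for neutrophil granules, 0.0670 for haem, 0.104 for immediate early, 0.125 for complement and 0.101 for proliferation. rag1 was at 6.35 ± 2.09 CPM and rag2 at 2.91 ± 1.9 (log2 −0.68 and −1.01).

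Over all blood cells of double mutants, 4 genes fell and 1 rose (5 of 14380, 891 at an unadjusted p under 0.05, DESeq2 55). ccl38.6, a chemokine that marked NK-lysin cell-like cells, fell from 50.2 ± 24.8 to 0.739 ± 0.350 CPM (log2 −5.36, SE 0.69, adjusted p = 0.0423). An uncharacterised si.dkey gene that was a leading gene of the B cell-like cluster fell to 1 UMI, a ratio of 0.00317 (counting interval 7.99e-05 to 0.0178, adjusted p = 0.0382). BX784026.1, a leading gene of the T cell-like cluster, fell from 17.8 ± 3.77 to 0.445 ± 0.167 CPM (log2 −5.01, SE 0.62), and lipia, a lipase gene, to 2 UMIs, a ratio of 0.0148 (0.00178 to 0.0544; adjusted p = 0.0382 for both). si.dkey.102m7.3 was fitted as a rise (log2 5.02, SE 0.49, adjusted p = 0.0172) with 15.7 ± 0.705 CPM against 16.8 ± 14.5 in wild type, where wild type 3 was at 0.687. BX784026.1 and lipia have a mean under the 20 CPM of the naming rule and were chosen after their values were seen. All 5 calls were lost without the version term, and in V3 animals alone, which hold 1 wild type animal. Leaving out wild type 1, double mutant 1 or double mutant 2 gave 0 calls, wild type 2 gave 1 and wild type 3 gave 2.

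In double mutants camera called 6 lists over all blood cells at the preset correlation and 0 with an estimated correlation, fry called 0, and mixed fry called 1, the cytotoxic genes (adjusted p = 0.0220). Of 7 cytotoxic genes 6 were negative (camera adjusted p = 0.00356; 0.173 with an estimated correlation). Over all genes 1 fell, ccl38.6, and adjusted over the list alone gzma fell as well. Of 8 MHC class II genes 7 were negative (0.00168; 0.215 with an estimated correlation), with cd74a, the invariant chain, at 194 ± 85.4 CPM against 2064 ± 1571 (log2 −1.37, SE 0.43) and ciita at −2.01 (SE 0.53), both of which fell adjusted over the list alone. Beside this, macrophage-like cells were at 7.29% against 21.3% in wild type, dendritic-like cells at 0.554% against 1.36% and B cell-like cells at 0 against 5.05%. All 12 inflammatory genes were negative (0.00168; 0.215 with an estimated correlation), and socs3a, a feedback inhibitor of cytokine signalling, fell adjusted over the list alone, from 527 ± 212 to 63.1 ± 26.7 CPM (log2 −2.07, SE 0.45, adjusted p = 0.347 over all genes). Of 22 immediate early genes 21 were negative (1.82e-07; 0.173 with an estimated correlation), fosab at 17.7 ± 5.30 against 192 ± 146 CPM. Camera also called common gamma chain (11 of 15 negative, il21r.1 at −4.45; 0.0269, and 0.385 with an estimated correlation) and interferon genes (16 of 19 negative; 0.0360, and 0.593 with an estimated correlation). In the p53 list cdkn1a, a cell cycle inhibitor, fell adjusted over the list alone (4.49 ± 2.34 to 0.293 ± 0.183 CPM), and the list was not called (0.703). Nor were end joining (0.968), MHC class I (0.803), neutrophil granules (0.604), haem (0.0502), complement (0.604) and proliferation (0.968). rag1 and rag2 were at 6.41 ± 6.28 and 3.54 ± 1.77 CPM (adjusted p = 0.902 for rag2).

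Over all blood cells, double mutants were also set against each single mutant, a comparison added after the data were seen. Against prkdc mutants 1 gene was called, si.dkey.102m7.3 (log2 4.99, adjusted p = 0.0211; 518 at an unadjusted p under 0.05). Its mean was nevertheless 15.7 CPM in double mutants and 17.5 in prkdc mutants, with prkdc mutant 3 at 0.38 CPM and prkdc mutants 1 and 2 at 29.2 and 22.9. Against il2rga mutants 5 were (831 at an unadjusted p under 0.05). lect2l was higher in double mutants, at 6507 ± 654.1 CPM against 153 ± 77.5 (log2 5.53, SE 0.65, adjusted p = 0.0285), as was csad (log2 6.34, SE 0.47, adjusted p = 0.00129). Lower were POU2AF1, a transcriptional coactivator of B cells, at 2.26 ± 0.188 against 55.7 ± 33.0 CPM (log2 −4.49, SE 0.54, adjusted p = 0.0285), the uncharacterised gene si.dkey.234i14.9 (adjusted p = 0.0435) and the B cell-like cluster gene already given (adjusted p = 0.0284). Each of these lower genes was a leading gene of the B cell-like cluster at resolution 1 and without lymphoid genes. Their falls move with the B cell-like cells, 0 in double mutants against 242 in il2rga mutants.

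Within cell types of prkdc mutants 1 gene was called in 7 classes, in the mycb cluster, whose leading gene is a Myc transcription factor. si.dkey.188i13.7, named ifi27.4 in the RefSeq table and a member of an interferon-inducible family, rose from 5.22 ± 2.62 CPM (n = 2) to 128 ± 160 (n = 3), with 26.3, 45.0 and 313 CPM in prkdc mutants 1, 2 and 3 (log2 5.65, SE 0.70, adjusted p = 0.00410). The other classes gave 0 calls and the 7 classes 1724 genes at an unadjusted p under 0.05, with 25 calls by DESeq2 over all 7. The call was lost without wild type 3 (log2 3.30), which left 1 wild type animal in this cluster, and without prkdc mutant 3 (log2 3.31, adjusted p = 1). It was also lost without the version term (0.725) and with at least 10 cells per class (0.271), and in 5 of 14 alternatives in all. Leaving out wild type 1, 2 or 3 gave 42, 103 or 7 calls in place of 1, and leaving out prkdc mutant 1, 2 or 3 gave 11, 29 or 6.

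Lists within classes of prkdc mutants were called by camera in 15 of 73 tests and in 0 with an estimated correlation. In erythroid-like cells 15 of 16 proliferation genes were negative (5.66e-07; adjusted p = 0.0617 with an estimated correlation), with ccnb1 and mki67 falling adjusted over the list alone, and 10 of 10 interferon genes were positive (1.17e-05; 0.341 with an estimated correlation). In neutrophil-like cells 7 of 8 inflammatory genes were negative (0.00148; 0.127 with an estimated correlation), with il1b and mmp9 falling adjusted over the list alone, and in macrophage-like cells 9 of 10 were negative (0.00156; 0.506 with an estimated correlation). Different clusters held these classes: the largest neutrophil-like cluster was 3, 21 and 0 in wild type 1, 2 and 3 and 1, 1 and 0 in prkdc mutants 1, 2 and 3, and clusters 3 and 21 were led by inflammatory genes. Wild type 2 held 261 of the 313 cells of macrophage-like cluster 14, led by irg1, and 290 of the 301 of cluster 16, led by grn2, and the prkdc mutants 4 and 8. The largest erythroid-like cluster was 5 and 7 in wild type 2 and 3 and 5, 2 and 2 in prkdc mutants 1, 2 and 3.

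Within cell types of il2rga mutants, 6 of 7303 genes rose and 11 fell in erythroid-like cells. ucp3, a mitochondrial uncoupling protein gene, rose from 0.694 ± 0.982 CPM (n = 2, wild type 2 and 3) to 227 ± 51.2 (n = 2; 1 against 419 UMIs, ratio 612, counting interval 109 to 24225; log2 9.23, SE 0.90, adjusted p = 0.000437). The mitotic kinase gene cdk1 fell from 266 ± 18.2 to 39.3 ± 9.32 CPM (log2 −2.75, SE 0.46), the proliferation marker mki67 from 422 ± 219 to 123 ± 12 (log2 −2.17, SE 0.37), and kif11, ube2c and cdca5, which act in mitosis, to 25.6 ± 5.86, 24.5 ± 9.37 and 6.68 ± 1.03 CPM (log2 −2.31, −2.59 and −3.28; adjusted p = 0.0423 for all 5). The largest fitted falls also included pdia6, a protein disulfide isomerase gene (log2 −4.99, but −3.20 without wild type 3 and −9.76 without il2rga mutant 2; wild type 2 at 8.33 CPM and wild type 3 at 116), prdx1, a peroxiredoxin gene, at least 29.9-fold lower (131 against 0 UMIs; wild type 2 at 9.72 CPM and wild type 3 at 71.2), and riok3, at least 17.3-fold lower (76 against 0 UMIs). The risers included the membrane transporter gene slc6a13l (4.38 ± 0.302 to 82.8 ± 0.81 CPM, log2 4.28) and pttg1ipb, at least 57.4-fold higher (0 against 118 UMIs). cdk1, mki67, kif11 and ube2c were outside the naming rule and were chosen after their values were seen. Their calls were not followed through the alternatives, so they are not shown to be sturdier than the lost calls given below. Of 16 proliferation genes 15 were negative, 2 fell over all genes and 8 fell adjusted over the list alone, among them top2a, tyms and rrm2. The list was called by camera (2.70e-09), with an estimated correlation (adjusted p = 0.0367 with an estimated correlation), by fry (0.0301) and by mixed fry (0.000307). These tests used the same animals, and lists were not tested again with an animal left out. Wild type 2 and 3 were also the reference for erythroid-like cells of prkdc and double mutants. There 15 and 16 of 16 proliferation genes were negative too, so the fall is not shown to be particular to il2rga mutants. The largest erythroid-like cluster was 7, led by plk1 and cdk1, in wild type 3 (35.5%), 5 in wild type 2 (30.9%), 6 in il2rga mutant 1 (40.9%) and 2 in il2rga mutant 2 (47.5%). In all blood cells together ucp3 was at 12.2 CPM in wild type 1, where the erythroid-like cells held 0 UMIs of it. It was at 13.4 and 77.7 CPM in il2rga mutants 1 and 2 and 0.486 to 3.69 in the other animals without the allele. The ucp3 call was lost without wild type 3 (log2 7.56, adjusted p = 0.487), and the cdca5 call without wild type 3 (0.487), il2rga mutant 1 (0.176) or il2rga mutant 2 (0.0697). The calls of pdia6, prdx1, riok3, slc6a13l and pttg1ipb were also lost without wild type 3, il2rga mutant 1 or il2rga mutant 2. Leaving out any of these animals left 1 animal of its genotype in the fit. Those calls were lost too without the version term (adjusted p 0.0527 to 0.133). In all, the calls of cdca5 and of these genes were each lost in 5 or 6 of 12 alternatives.

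Neutrophil-like cells of il2rga mutants differed in 1 of 8784 genes. lect2l, a leukocyte chemotaxin-like gene that marks neutrophils, fell from 19548 ± 10430 CPM in wild type (n = 3) to 616 ± 191 (n = 2), against 25440 ± 6174 in prkdc mutants and 32173 ± 68.0 in double mutants (log2 −4.75, SE 0.47, adjusted p = 0.00133). The largest neutrophil-like cluster was 0 in wild type 3 and in both il2rga mutants, and 3 and 21 in wild type 1 and 2. The call was lost without il2rga mutant 2 (log2 −4.52, adjusted p = 0.0944).

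**Figure D4:**
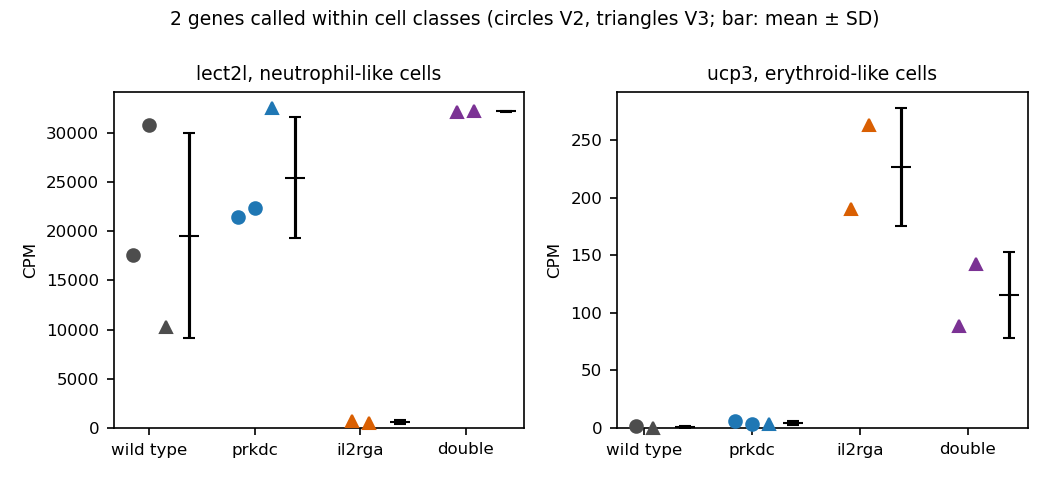
Level in CPM of lect2l in neutrophil-like cells and of ucp3 in erythroid-like cells by genotype, with each point 1 animal (circles V2, triangles V3) and bars for the mean ± SD; wild type 1 has no ucp3 value because it had under 20 erythroid-like cells. lect2l averaged 616 CPM in il2rga mutants and 19548 CPM in wild type, and ucp3 averaged 227 CPM in il2rga mutants and 116 CPM in double mutants against 0.694 CPM in wild type.

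Other classes of il2rga mutants gave few calls outside the mycb cluster, where 7 genes rose and 6 fell of 5137. Risers included si.dkey.188i13.7 (log2 3.89; 87.0 ± 16 CPM), lost without wild type 3 (adjusted p = 0.836), il2rga mutant 1 (0.0838) or il2rga mutant 2 (0.251), and sesn1, a sestrin gene (log2 2.92), chosen after its values were seen. Fallers included cahz, a carbonic anhydrase gene (801 ± 124 to 36.7 ± 5.24 CPM, log2 −3.72), rrm2, a subunit of ribonucleotide reductase (log2 −3.18), and hsp90aa1.2, a cytosolic chaperone gene, which stood at 1678 CPM in wild type 3 and 0 in wild type 2 and reversed without wild type 3 (log2 3.95). The cahz and rrm2 calls were lost without wild type 3, il2rga mutant 1 or il2rga mutant 2. Each omission left a lone animal of its genotype in this cluster. The cahz and rrm2 calls were also lost with at least 10 cells per class (adjusted p = 0.187 and 0.169). HSC and progenitor-like cells had 1 call, si.dkey.102m7.3 (log2 8.03, SE 1.21, adjusted p = 0.0206), which was lost without the version term (log2 0.80) and without wild type 2 (0.0707), wild type 3 (0.127) or il2rga mutant 1 (0.0574). edgeR's quasi-likelihood test called 0 genes in B cell-like cells (73 at an unadjusted p under 0.05) and 0 in macrophage-like cells (380), and DESeq2 called 193 over all 6 classes, where edgeR called 32. Leaving out wild type 2 gave 233 calls, wild type 3 gave 2 and il2rga mutant 1 gave 6. In erythroid-like cells camera also called MHC class II genes upward (6 of 6; 0.000705, and 0.234 with an estimated correlation) and haem genes downward (11 of 13; 0.0131, and 0.360 with an estimated correlation).

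Within cell types of double mutants 2 genes were called in 6 classes (2110 at an unadjusted p under 0.05, DESeq2 22). ucp3 rose in erythroid-like cells to 116 ± 37.6 CPM (n = 2; ratio 274, counting interval 48.9 to 10824; log2 8.24, SE 0.90, adjusted p = 0.00175), and hsp90aa1.2 fell in the mycb cluster (log2 −5.37, SE 0.75, adjusted p = 0.0179), a call that reversed without wild type 3 (log2 4.25). Without wild type 3, which left a lone wild type animal in the erythroid-like fit, the ucp3 call was lost (log2 6.62). All 16 proliferation genes were negative in erythroid-like cells (7.27e-07; adjusted p = 0.0737 with an estimated correlation). In neutrophil-like cells 7 of 8 MHC class II and 7 of 8 inflammatory genes were negative (0.0244 and 0.0265; 0.226 with an estimated correlation for both). The largest neutrophil-like cluster was 0 in both double mutants and in wild type 3, and 3 and 21 in wild type 1 and 2. The largest erythroid-like cluster was 6 in double mutant 1 (35.0%) and 2 in double mutant 2 (26.9%). Leaving out wild type 2 or 3 gave 65 or 13 calls, wild type 1 gave 35, and double mutant 1 or 2 gave 11 or 31.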

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

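The tests of the meiotic cells and the test of the interaction in single genes over all blood cells were chosen only after the results were seen.

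csad, the taurine synthesis gene, was the only 1 of 14380 genes called for the interaction of the mutations over all blood cells (log2 5.65, SE 0.61, adjusted p = 0.0431; 567 at an unadjusted p under 0.05). It was at 66.3 and 58.3 CPM in double mutants, 0.912 and 0.696 in il2rga mutants, 20.1 in wild type 3, 26.6 in prkdc mutant 3 and 0.324 to 1.23 in the V2 animals.

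Cells led by meiotic genes such as sycp1, which encodes a protein of the synaptonemal complex, were outside the blood and kidney comparisons and stood out in single animals. They made up 6.07% of cells in prkdc mutant 1 (58 of 955; exact interval 4.64% to 7.78%) and 2.71% in double mutant 2 (27 of 997; 1.79% to 3.92%). The highest wild type value was 0.655% (7 of 1069; 0.264% to 1.34%) in wild type 3, wild type 1 had 0.150% (2 of 1333), and the other animals had 0.

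Kidney epithelium was argued against, because the summed nephron epithelium markers stood at 165 CPM in these cells, against 6432 CPM in the tubule clusters (a ratio of 0.0257) and 8150 CPM in the 20 cells of the kidney multiciliated cluster. Genes of cilia were high in them all the same: 10 of 11 multiciliated markers were at least 4-fold above blood cells, with odf3b at 1629 and tekt1 at 1283 CPM against 290 and 137 in the multiciliated cluster, and foxj1a at 248 against 580. Germ cell genes set the meiotic cells apart from that cluster. sycp3, syce2 and hormad1 were at 1035, 1296 and 839 CPM in the meiotic cells and 0 in the multiciliated cluster. dazl was at 276 against 15.3 CPM, and tex15 at 0 in both. Ciliated cells of another kind that lack nephron epithelium markers were not excluded. The prkdc allele alone was argued against as well, because the lowest share among animals with the allele was 0%, below the 0.655% of wild type 3. Germ cells carried over with the tissue may account for the cluster: 13 of 14 measured germ cell genes (92.9%) were at least 4-fold above blood cells. The list holds meiotic genes and was tested after the cluster was seen to be led by such genes, so it is not independent support. No sex or stage of the animals was tested, and carry-over of germ cells remains a hypothesis.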

How the results depend on the processing

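Clustering at resolution 1 or without lymphoid genes, leaving out doublet-like cells or the si.dkeyp.75b4.10 and cfd clusters, leaving out animals for the interaction and the wild type shares, and the alternatives for the targeted genes were chosen only after the results were seen. Among classes, the falls of B cell-like cells in double mutants against wild type (fitted log2 −9.37 to −6.80, set by the model for a count of 0) and against il2rga mutants, and of T cell-like cells in double mutants against wild type, kept direction and call under each alternative that gave a value. At resolution 1 no T cell-like cluster formed: the cluster with NK-lysin genes held 229 T cell-like and 245 NK-lysin cell-like cells, so its values are of both together and are not compared with NK-lysin cell-like cells. Classes with fewer than 20 cells over all animals were not tested. T cell-like cells therefore gave no value in cells above the median UMI count, in any comparison. A lower number of classes in that setting is not a tested loss of a T call. The targeted gene il2rga rested on at most 26 UMIs per genotype, and 0 of the genes changed 2-fold in simulated blood cells were recovered. With V3 animals alone, or with 1 il2rga or double mutant left out, a lone animal is assumed to vary like the others. The same was assumed within classes where few animals had at least 20 cells. Wild type 1 had under 20 erythroid-like and mycb cells, so leaving out either other wild type animal left a lone wild type animal there. In the si.dkeyp.75b4.10 cluster, wild type 2 and prkdc mutant 1 had under 20 cells, so leaving out another animal of their genotypes left a lone one. Where a value below moved, the cause was not tested, except that leaving out animals or using V2 or V3 animals alone leaves fewer animals.

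For prkdc mutants against wild type, B cell-like cells stayed between log2 −5.21 and −3.48 (adjusted p up to 0.114). With V3 animals alone 0 classes were called (B −4.18, adjusted p = 0.114; T −2.45, 0.50). With V2 animals alone 1 class was called (T −2.04, adjusted p = 0.230; NK-lysin −0.23). Cells above the median UMI count (T cell-like cells not tested), resolution 1 (joint T and NK-lysin cluster −0.75) and clustering without lymphoid genes (T −2.13, adjusted p = 0.0695) each gave 1 class. Leaving out 1 animal gave 1 to 2 classes, T cell-like values of −2.50 (without wild type 2) to −1.76 (without wild type 1), with the call lost in 5 of 6, and NK-lysin values of −0.23 (without prkdc mutant 3) to 0.85 (without wild type 1).

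The animal numbers shared by wild type and prkdc animals were tested as a replicate block in 6 animals. Deviations of same-numbered animals correlated at 0.0144, 0.303 and 0.524, and wild type 1 correlated best with prkdc mutant 2 (0.415), so the numbers were not taken to pair the animals. The replicate block gave 0 classes (B −4.27, adjusted p = 0.0785; T −2.09, adjusted p = 0.0839) and 61 genes within classes.

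For il2rga mutants against wild type, no version term gave 3 classes, TMM over classes 2 and cells above the median UMI count 0 (B −0.36, with T cell-like cells not tested). Leaving out 1 animal gave 0 (without wild type 3) to 2 classes (without wild type 2), T cell-like values of −8.67 (without il2rga mutant 1) to −4.59 (without il2rga mutant 2) and B cell-like values of −0.51 (without il2rga mutant 1) to 1.54 (without il2rga mutant 2). For double mutants against wild type, cells above the median UMI count gave 1 class, again with T cell-like cells not tested.

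For double against prkdc mutants, 0 classes were called with TMM over classes (NK-lysin −2.67, adjusted p = 0.0862; T −4.11, 0.0653), cells above the median UMI count (NK-lysin −3.14, 0.267), DESeq2 (NK-lysin −2.96 and T −4.52, 0.0562 for both), V3 animals alone (NK-lysin −3.41, 0.0542; T −4.04, 0.106) and without lymphoid genes (NK-lysin −2.84 and T −3.69, 0.0631 for both), and 1 at resolution 1. Leaving out 1 animal gave 0 (without prkdc mutant 3) to 3 classes (without prkdc mutant 2), NK-lysin values of −4.47 (without double mutant 2) to −1.70 (without prkdc mutant 3) and T values of −6.47 (without double mutant 1) to −3.53 (without double mutant 2). For double against il2rga mutants, TMM over classes gave 2 classes, and the joint cluster at resolution 1 was at −0.0748. NK-lysin, not called at log2 0.08, was at −0.24 in cells above the median UMI count, −0.0625 without lymphoid genes and −1.45 (without double mutant 2) to 0.87 (without double mutant 1) with 1 animal left out. T cell-like cells were at −3.24 (without double mutant 1) to 2.27 (without il2rga mutant 1). The interaction gave 0 to 1 classes (without prkdc mutant 2), with NK-lysin at −1.77 (without double mutant 2) to 0.55 (without double mutant 1) and T at −1.07 (without double mutant 1) to 4.44 (without il2rga mutant 1).

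Wild type shares moved by over 1 SD in cells above the median UMI count: B cell-like 1.96%, rag1-high B cell-like 0.104%, HSC and progenitor-like 9.60%, NK-lysin cell-like 0.672%, T cell-like 0.981%, dendritic-like 0.945%, thrombocyte-like 1.05%, and the cfd, mycb and si.dkey.239h2.3 clusters 0.366%, 4.36% and 0.419%.

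Calls over all blood cells for prkdc, il2rga and double mutants numbered 32, 32 and 55 with DESeq2 and 3, 4 and 15 with no filter. No version term gave 0 and 0 for il2rga and double mutants, V3 animals alone 4 and 0, and thinned cells 0 and 1. Leaving out 1 animal gave 0 to 1, 0 to 2 and 0 to 2. In prkdc mutants, rag2 was at log2 0.0101 without the version term and 0.19 in V2 animals alone, and in V3 animals alone il1b was at 0.0434, nfkbiaa 0.26, mhc2dab 0.99 and rag1 −2.88. With 1 animal left out, rag1 was at −0.13 (without wild type 2) to 2.72 (without prkdc mutant 3) in prkdc mutants, −1.11 to 3.97 in il2rga mutants and −2.21 to 4.1 in double mutants, both highest without wild type 3. rag2 was at −0.88 (without prkdc mutant 2) to 0.19 (without prkdc mutant 3) in prkdc mutants and −1.20 to 0.31 (without wild type 3) in double mutants. The targeted gene il2rga was at −0.41 (without prkdc mutant 2) to 0.71 (without prkdc mutant 3) in prkdc mutants, −5.01 (without il2rga mutant 1) to 1.08 (without wild type 3) in il2rga mutants and −1.22 (without double mutant 2) to 0.61 (without wild type 3) in double mutants. prkdc in il2rga mutants was at −0.59 (without wild type 3) to 0.33 (without il2rga mutant 2). For single genes over all blood cells other than the targeted genes, 708 alternatives kept direction and side of the threshold, 45 lost it, 14 gained it and 16 reversed, all of rag1, rag2, il1b, nfkbiaa or mhc2dab. Most of these genes were never called, so the 708 do not measure how stable the calls were. All 45 losses were of called genes. In il2rga mutants csad lost its call in 5 of 13 alternatives and si.dkey.102m7.3 in 3. In double mutants, also of 13, si.dkey.102m7.3 lost it in 7 and ccl38.6 in 6. BX784026.1, lipia and the B cell-like cluster gene each lost it in 8.

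Calls within classes for prkdc, il2rga and double mutants numbered 25, 193 and 22 with DESeq2, 233, 373 and 143 with no filter, 182, 264 and 163 in V3 animals alone, and 0, 6 and 1 with no version term. At least 10 cells per class gave 2 and 6 for prkdc and il2rga mutants, and at least 50 cells 1 for double mutants. Leaving out 1 animal gave 6 (without prkdc mutant 3) to 103 (without wild type 2), 2 (without wild type 3) to 233 (without wild type 2) and 11 (without double mutant 1) to 65 (without wild type 2). Fits without wild type 2 or 3 held a lone wild type animal in erythroid-like and mycb cells, so those counts partly lack replicates. In the mycb cluster hsp90aa1.2 was at −6.02 (without wild type 2) to 3.95 (without wild type 3) in il2rga mutants and −6.20 (without double mutant 2) to 4.25 (without wild type 3) in double mutants. Gene lists called over all blood cells fell from 7, 1 and 6 to 0, 0 and 0 with an estimated correlation and with fry, and within classes from 15, 4 and 5 to 0, 1 and 0 with an estimated correlation and 1, 1 and 0 with fry. Mixed fry called 1, 0 and 1 over all blood cells and 1, 3 and 2 within classes.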

Other observations

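The tests of the il2rga allele and of paralogs for lect2l, and those of ucp2 and of the V3 protocol for ucp3, were chosen only after the results were seen, while the tests of a shared background, of a linked segment and of other splits of the animals were written before their results were seen.

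Some classes carried genes outside their marker sets. The unnamed cluster led by si.dkeyp.75b4.10 held 1421 ± 1097 CPM of agr2, a protein disulfide isomerase of secretory cells, and 480 ± 247 CPM of the transcription factor gata2a (wild type, n = 3). agr2 belongs to the fixed set for mucin cells of the kidney. At resolution 1 and without lymphoid genes, the cluster with this leading gene came closest to that set. It had 2 of the markers, short of the 3 needed. The cfd cluster held 517 CPM of agr2. Both clusters were counted as blood, and whether they are kidney cells was not tested. The si.dkeyp.75b4.10 cluster made up 1.12% ± 0.528 of blood cells in il2rga mutants (n = 2), 4.97% ± 1.95 in double mutants and 3.54% ± 2.32 in wild type (adjusted p = 0.0774 in il2rga mutants). Macrophage-like cluster 30 was led by hmox1a and slc40a1, genes of haem breakdown and iron export, and by marco. Cells with the keratin genes krt91 and krt4 made up 1.88% of wild type 1 (25 cells) and 1.47% of prkdc mutant 1 (14 cells) and were at 0 in the other animals. Globin RNA was counted in other classes too: ba1 averaged 7729.8 ± 11791 CPM in NK-lysin cell-like cells of wild type, with 21324 CPM in wild type 2.

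Genes of the major histocompatibility complex differed between single animals. mhc1uba was at 385, 260 and 170 CPM over all blood cells in prkdc mutant 1, il2rga mutant 1 and double mutant 1 and at most 2.43 elsewhere. mhc2dab was at 9.54 and 3.59 CPM in prkdc mutants 1 and 2 and at least 187 elsewhere. prf1.2, a perforin gene, was at 6.46 CPM in prkdc mutant 3 and 1.85 in prkdc mutant 1, and nkl.4 at 32.7 to 93.3 CPM in prkdc mutants, 36, 3.89 and 2.58 in wild type 1, 2 and 3 and 0.152 to 8.35 in il2rga and double mutants.

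The low lect2l in neutrophil-like cells of il2rga mutants was weighed against technical and genetic explanations. The il2rga allele in any background was argued against, since double mutants stood above il2rga mutants by log2 5.81 (SE 0.46, adjusted p = 0.000105, edgeR). Reads shared with the paralog LECT2_1_of_many were argued against, since the sum of both genes in the higher il2rga mutant was 0.177 of that in the lowest other animal. A genetic background shared by the il2rga mutants may contribute and stays open. The test counted genes that set this pair of animals at least 8-fold apart from the rest and found 1, which was lect2l itself (0 without it), so it decided nothing; 7 of 44 other pairs had as many or more, with at most 2. An effect that needs il2rga loss with intact prkdc also stays open, since the design confounds it with that background.

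The high ucp3 in erythroid-like cells of both genotypes with the il2rga allele was weighed in the same way. The V3 protocol was argued against, since the highest V3 animal without the allele had 0.0349 of the lowest carrier's ucp3. Reads moved from the paralog ucp2 were argued against among V3 animals, where the sum of both genes in the lowest carrier was 11.5 times that in the highest animal without the allele, although V2 animals without it had 21.6 to 106 CPM of that sum and carriers 95.3 to 264. A segment carried with the allele could not be excluded: 1 of the 50 tested neighbours of il2rga on chromosome 10 had p under 0.05, against a median of 2 in 216 other windows. That met the outcome written against a segment, but windows at 1 or more were 84.3% and the 5th percentile was 0, and the 50 neighbours do not reach ucp3, 126 genes away.

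Other splits of the 6 wild type and prkdc animals were compared with the real one. The 10 possible splits are too few for a share under 0.05. For cell composition the real split called 2 classes and the highest other 0, so 1 of 10 splits gave as many. Over all blood cells the real split called 0 genes and the highest other 36, in wild type 1 with prkdc mutants 1 and 2 against the rest, and since the real count was 0, all 10 of 10 gave as many whatever the data, which tests nothing. Within classes the real split called 1 gene and some other splits called more, the most in wild type 1 with prkdc mutants 2 and 3. These totals are not like for like, because the animals with at least 20 cells differ by class. In the unnamed cluster with agr2 described above, only wild type 1 and 3 and prkdc mutants 2 and 3 had that many. There the split with the most calls leaves wild type 3 alone against 3 animals. The totals therefore do not decide whether the animals differ in ways other than genotype, and what such differences are was not tested. Leaving out 1 animal from the real split changed the number of calls too, as given above.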
